A study of Arabidopsis thaliana with 4 samples.

How the data were processed

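RNA was extracted from whole 9-day-old *Arabidopsis thaliana* Col-0 seedlings grown on MS plates with 16 h of light and 8 h of dark at 23 ± 2 °C, and mRNA was taken up on poly-T beads and made into libraries with a directional kit for an Illumina HiSeq instrument, per the labels' protocols. There were 2 libraries from wild type and 2 from the mutant trm4b-4. The mutants' genotype field spells the allele tm4b-4, while the titles spell it trm4b-4, and both were taken as the same group. TopHat2 2.0.12, Cufflinks 2.1.1, HTSeq 0.6.1 and Cuffdiff are named with the TAIR10 build, per the submitters' processing notes. The role and order of these tools, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Genes that share reads with a near-identical copy (such as *LHCB1.1* and *LHCB1.2*, the *RBCS* genes, *IMA1* and *IMA2*, *COR15A* and *COR15B*, *KIN1* and *KIN2*) and genes that overlap another gene on the opposite strand are therefore uncertain.

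The deposited values were fragments normalised to gene length and library total (FPKM), 1 file per library with 33664 features each, including 62 named as new, 133 of the plastid and 146 of the mitochondrion. The file headers name only the library, and the values do not tell FPKM from RPKM. The unit was read from the values, which equal a whole number of fragments divided by a whole gene length and a whole library total. The totals were recovered from 1386 genes, 413 of them with over 100 fragments, and their estimates varied by at most 0.00349 fragments (SD). All 24892 features above 0 in any library gave whole fragments in the 4 libraries, within 2e-06 fragments plus a relative 3e-09. The length used was an annotated one for 3787 features. For the others it was the largest multiple of the smallest step that did not exceed the longest annotated transcript, so their fragment numbers are estimates that can be off by a whole factor. The recovered fragments summed to between 101.47% and 101.56% of each total. The total was 26390263 fragments for wild type replicate 1 and 23782269 for replicate 2, and 21931590 and 23068982 for trm4b-4 replicates 1 and 2. Intervals and floors cover counting error only, because fragments were summed over the libraries of a genotype and the spread between them was not modelled. PCR copies were not marked either. Genes near absent from a genotype were picked by the same fragments, so their intervals need not hold at 95%.

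Tests were run on log2(FPKM + 1), so a fold change on this scale understates the change of genes with low values. Genes at 1 FPKM or more in at least 2 of the 4 libraries were tested, 19027 in all, with limma 3.58.1 in R 4.3.3, using an empirical Bayes fit with a mean-variance trend, no covariate and a two-sided Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera in limma at a preset correlation of 0.01 and adjusted over the lists with 3 or more tested members. The same test with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction, were run beside it. With an estimated correlation camera takes its p from the 2 residual degrees of freedom, so few lists can pass whatever their correlation. The design, the main alternatives, the rule for named genes and 32 lists with 385 members were fixed before the data were examined. Plastid-encoded and mitochondrion-encoded genes formed the other two lists. By the fixed matching rule, 8 members were dropped because the reference gave their locus another symbol without listing theirs (*TRDMT1*, *NOP2A*, *MTB*, *VIR*, *HSP70-4*, *HSP22*, *HSP23.6* and *FIT*), which left 377. Names came from the annotation of TAIR10.1, in which 32835 features were matched by locus. Positions are those of TAIR10.1 and were used only to describe where a gene lies.

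Named genes were *TRM4B*, *TRM4A*, *SHY2* and *IAA16*, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, and from each list up to 2 members per direction with the smallest adjusted p. Where a count was 5 or fewer, other members are named as well, and these were chosen after their values were seen. Some genes that the rule names are not reported here. Lists for root hairs, root endodermis and suberin, seed storage, floral identity and nuclear photosynthesis stood for organs or cell types. Lists for rapid stress and touch and for the clock stood for handling and time of harvest.

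The procedure was tested on data simulated for trm4b-4 against wild type, with 18996 genes tested and 200 changed. It called 73.1% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold. Of its 199 calls, 22 (11.1%) were unchanged genes, above the nominal 5%. Every simulated gene had the same dispersion, 0.000265, taken from the spread between libraries of a genotype. The 200 changed genes were also far fewer than the 6530 called in the data. These rates therefore do not give the error of the real comparison. In the camera test, 3.5% of 200 unchanged sets of 10 genes had a p under 0.05. Alternatives were a replicate block, each library left out, other pseudocounts, filters, scalings and variance models, nuclear genes only and a minimum fold of 2. Voom on the recovered fragments, a test against a fold of 1.5 and removal of GC and length trends (18848 genes tested, 99.1% of the 19027) were added after the data were seen. Recovery and counting intervals used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.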

Results

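Transcript levels were measured by poly(A) RNA sequencing in whole Arabidopsis seedlings of the wild type Col-0 and of trm4b-4, a mutant in *TRM4B* (AT2G22400), which encodes a methyltransferase that places 5-methylcytosine in RNA. Each genotype had 2 libraries, with 21931590 to 26390263 counted fragments each, and between 18785 and 18888 genes per library reached 1 FPKM. Libraries of a genotype were close to each other. The mean chi-square per gene was 1.71 between the wild-type libraries and 1.57 between the trm4b-4 libraries, against 26.8 to 28.4 between genotypes. The median, relative to that of sampling alone, was 1.37 and 1.34 within genotypes, against 5.49 to 5.69 between them. The labels do not say whether the libraries of a genotype came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

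*TRM4B* was higher, not lower, in the libraries labelled trm4b-4. Its level was 29.3 ± 0.541 FPKM in wild type and 86.7 ± 0.586 FPKM in the libraries labelled trm4b-4 (SD, n = 2 each), a ratio of 2.96 (log2 change 1.53, SE 0.034, limma adjusted p = 2.4e-08). The gene lies on chromosome 2 at 9504659 to 9508895 (TAIR10.1), on the minus strand, and gene-level values do not show which part of it was read. Its paralog *TRM4A* (AT4G40000) went from 1.6 ± 0.0721 to 2.89 ± 0.352 FPKM (log2 change 0.58, adjusted p = 0.00554). Every direction below refers to the genotype on the label, and the level of the targeted gene does not by itself identify the mutant libraries.

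**Figure D1:**
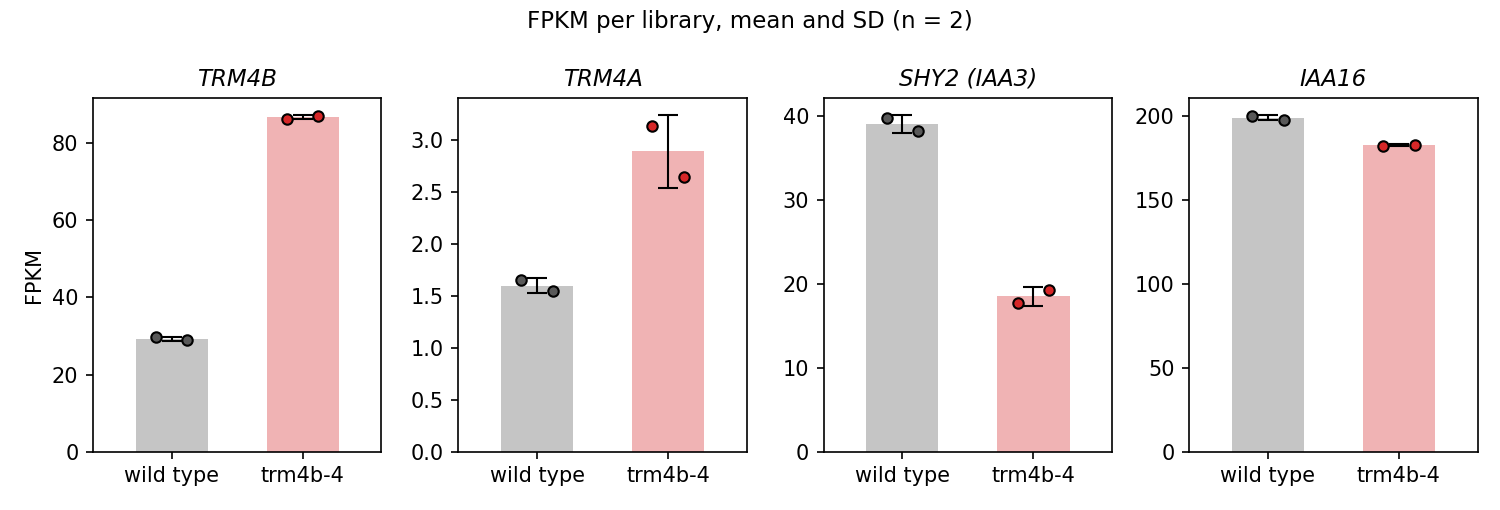
FPKM of 4 genes in each library (points), with the mean (bar) and SD (error bar) of the 2 libraries per genotype. *TRM4B* and *TRM4A* were higher and *SHY2* was lower in the libraries labelled trm4b-4, while *IAA16* lay between 182.5 and 200.4 FPKM in all 4 libraries.

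All 5 tested members of the RNA 5-methylcytosine methyltransferase list rose (median log2 change 0.58, camera adjusted p = 0.00168, adjusted p = 0.54 with an estimated correlation). Beside *TRM4B* and *TRM4A* these were *NOP2B* (0.59), *NSUN5* (0.35) and *NOP2C* (0.24). The list holds the targeted gene itself, so its call is not independent of the rise of *TRM4B*. The rise of *TRM4A* may not be independent either, because how reads matching both paralogs were counted is not given. Without a filter 4 of 6 tested members rose (median 0.47). *TRDMT1* and *NOP2A*, dropped by the matching rule, are not covered by these counts. Of 8 genes for writing, reading or removing N6-methyladenosine, 4 rose, the demethylase gene *ALKBH10B* (0.43) and the reader genes *ECT4* (0.22), *ECT2* (0.19) and *ECT3* (0.13), with a camera adjusted p of 0.0917. Only 3 rose after median-of-ratios rescaling or removal of GC and length trends, and 5 with nuclear genes only or voom. Among the 10 tested genes nearest to *TRM4B*, 6 passed the test, in both directions, where 34.3% of all tested genes passed. *RABA4E* (AT2G22390) beside it was lower (log2 change -0.59, adjusted p = 0.00565) and *SLO1* on the other side was at 0.21 (adjusted p = 0.193). None of the 10 passed a test against a fold of 1.5.

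In the libraries labelled trm4b-4, 14 of 14 genes induced within minutes by touch, wounding or other stress were lower, and 11 of 12 iron-deficiency, 7 of 10 flavonoid and anthocyanin and 5 of 5 tested seed storage genes were higher. With an estimated correlation none of these 4 lists passed (adjusted p = 0.303, 0.332, 0.524 and 0.54). Across the genome 6530 of 19027 tested genes (34.3%) passed the test, 3648 higher and 2882 lower. Most changes were small: 82.3% of the called genes changed by less than 1.5-fold, and the median size was 0.31 on the log2 scale. Among called genes with at least a 2-fold change, 114 rose and 300 fell, and at 4-fold or more 10 rose and 53 fell. These folds are of FPKM + 1, which understates changes of genes with low values. The median log2 change of all tested genes was 0.031. A test against a fold of 1.5 left 120 genes higher and 332 lower.

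**Figure D2:**
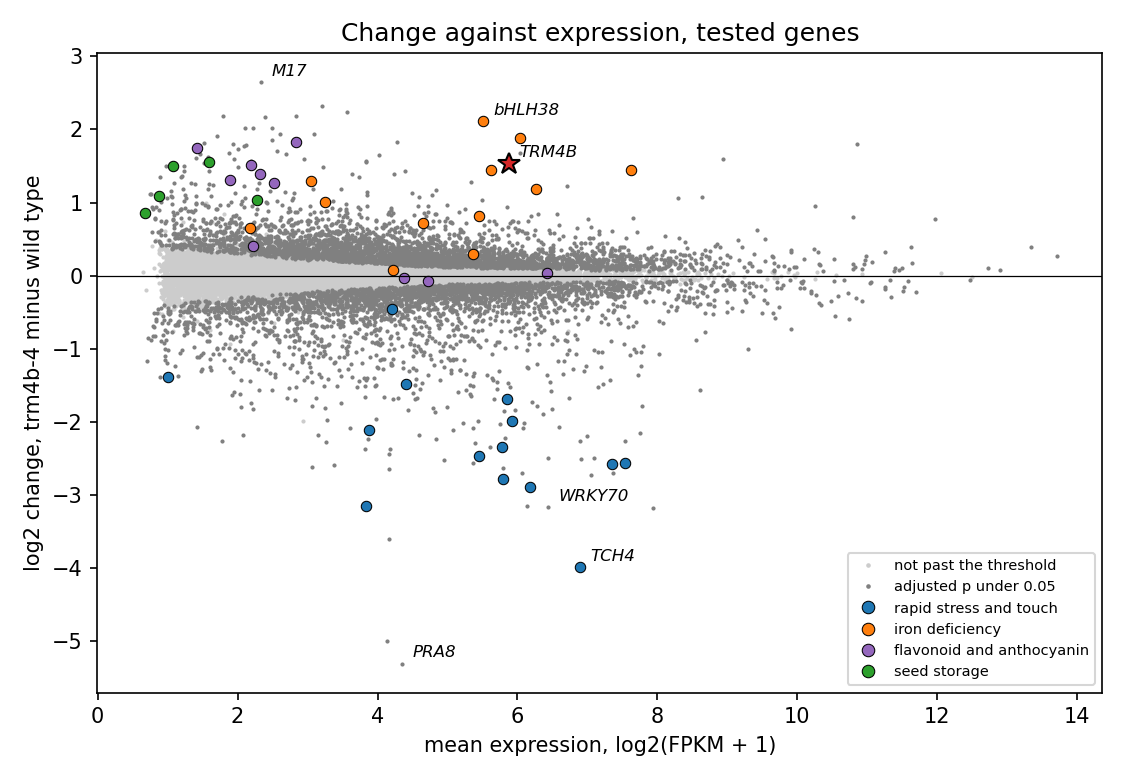
Log2 change (libraries labelled trm4b-4 minus wild type, FPKM + 1) against mean expression for the 19027 tested genes, with 4 lists in colour and *TRM4B* as a star. The rapid stress and touch genes lie below 0 at all expression levels, and the iron-deficiency, seed storage and most anthocyanin genes lie above it. The plotted value of *PRA8* depends on the added 1 because no fragment was counted in the libraries labelled trm4b-4.

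On the log2(FPKM + 1) scale the largest rise was that of *M17* (AT2G41260), encoding a late embryogenesis abundant protein, which went from 0.378 ± 0.0571 to 7.68 ± 1.15 FPKM (log2 change 2.65, FPKM ratio 20.3). For genes with low values this scale shows less change than the FPKM ratios used for the falls below. The MATE efflux gene AT2G04050 rose by 2.33. *LEA18* went from 3.15 ± 0.0579 to 18.6 ± 0.821 FPKM (2.24) and *LEA7* from 1.56 ± 0.29 to 10.7 ± 0.333 FPKM (2.19). *BETA-TIP*, a tonoplast water channel gene of seeds, rose by 2.02, the metallothionein gene *AtMT4b* by 2.03 and the AWPM-19-like gene AT1G04560 by 2.17. The remaining genes among the 10 were AT4G12735 (2.18, FPKM ratio 17.9), the iron-response regulator *bHLH38* (2.11) and the glycine-rich protein gene AT5G35660 (2.02). The largest limma adjusted p among the 10 was 2.52e-05, for AT4G12735. *M17*, AT4G12735 and AT5G35660 were under 1 FPKM in both wild-type libraries. They passed the filter only through the libraries labelled trm4b-4, so their direction was largely set by the filter.

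Of the 10 largest falls, 2 were near-complete losses. *PRA8* (AT3G13720, chromosome 3, 4494979 to 4496800 in TAIR10.1), which encodes a prenylated Rab acceptor, had 995 and 830 fragments in wild type and 0 in both libraries labelled trm4b-4. With a floor of 3 fragments over the group it was 546-fold lower, and the exact 95% interval of the ratio began at 443. The non-coding RNA gene AT2G01422 (chromosome 2, 183940 to 184734) had 571 and 531 fragments against 0 and 2, a ratio of 494 (exact 95% interval 136 to 4090). The other 8 genes kept a measurable level. *TCH4*, a touch-induced xyloglucan-modifying enzyme gene, went from 223 ± 4.11 to 13.2 ± 0.236 FPKM, 17.0 times lower. The abscisic acid catabolism gene *CYP707A3* was 18.6 times lower, the calmodulin-like gene *CML38* 13.1 times, the EF-hand gene AT4G27280 9.23 times, *WRKY70* 9.47 times and *MYB77* 9.51 times. The ethylene response factor genes *ERF6* and *ERF105* were 7.82 and 7.34 times lower.

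Every member of the rapid stress and touch list fell, 14 of 14, by a median of -2.40 on the log2 scale (camera adjusted p = 7.12e-21, adjusted p = 0.303 with an estimated correlation). The range ran from -3.99 for *TCH4* to -0.46 for the zinc finger gene *ZAT12*. *TCH3*, a calmodulin-like gene, went from 279 ± 2.23 to 45.8 ± 0.86 FPKM. The jasmonate list moved with it, with 12 of 15 members lower, 2 higher and a median of -0.57 (camera adjusted p = 2.29e-06, adjusted p = 0.512 with an estimated correlation). All 7 tested *JAZ* repressor genes of the list fell, including *JAZ7* (-2.19), *JAZ9* (-1.99) and *JAZ1* (-1.14), as did *MYC2*. The members that rose were the defensin gene *PDF1.2* (1.82) and the lipoxygenase gene *LOX2* (0.12). *PDF1.2* was under 1 FPKM in both wild-type libraries and passed the filter only through the libraries labelled trm4b-4. *LOX2* lost its call without the mean-variance trend (adjusted p = 0.128) and with GC and length trends removed (log2 change 0.06, adjusted p = 0.0575). Of 12 salicylic acid and defence genes, 7 fell and 1 rose (median -0.27, camera adjusted p = 0.00168, adjusted p = 0.54 with an estimated correlation). *WRKY70* (-3.17) and *WRKY53* (-1.57) fell most, and the salicylic acid synthesis gene *ICS1* rose (0.59). In the ethylene list *ERF2* fell by 1.84 on the log2 scale and *EBF2* rose by 0.13, with no call for the list (camera adjusted p = 0.641). The call of *EBF2* was lost without any of the 4 libraries in turn (log2 change 0.111 to 0.149). It was also lost after median-of-ratios rescaling (0.098, adjusted p = 0.0868) and without the mean-variance trend (0.13, adjusted p = 0.106). With GC and length trends removed its change was 0.078 (adjusted p = 0.156).

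Clock genes differed between the same libraries. In the morning list 4 of 5 rose, *CCA1* by 0.92, *PRR9* by 0.88, *RVE8* by 0.62 and *PRR7* by 0.12, and *RVE1* fell (-0.55), with a camera adjusted p of 0.131. Only 3 morning clock genes rose after median-of-ratios rescaling or removal of GC and length trends, and *RVE1* lost its call without wild type replicate 2 (adjusted p = 0.069). In the evening list 3 of 9 rose, including *FKF1* (0.34) and *GI* (0.33), and 4 fell, including *BOA* (-0.82) and *TOC1* (-0.29), with a camera adjusted p of 0.383.

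**Figure D3:**
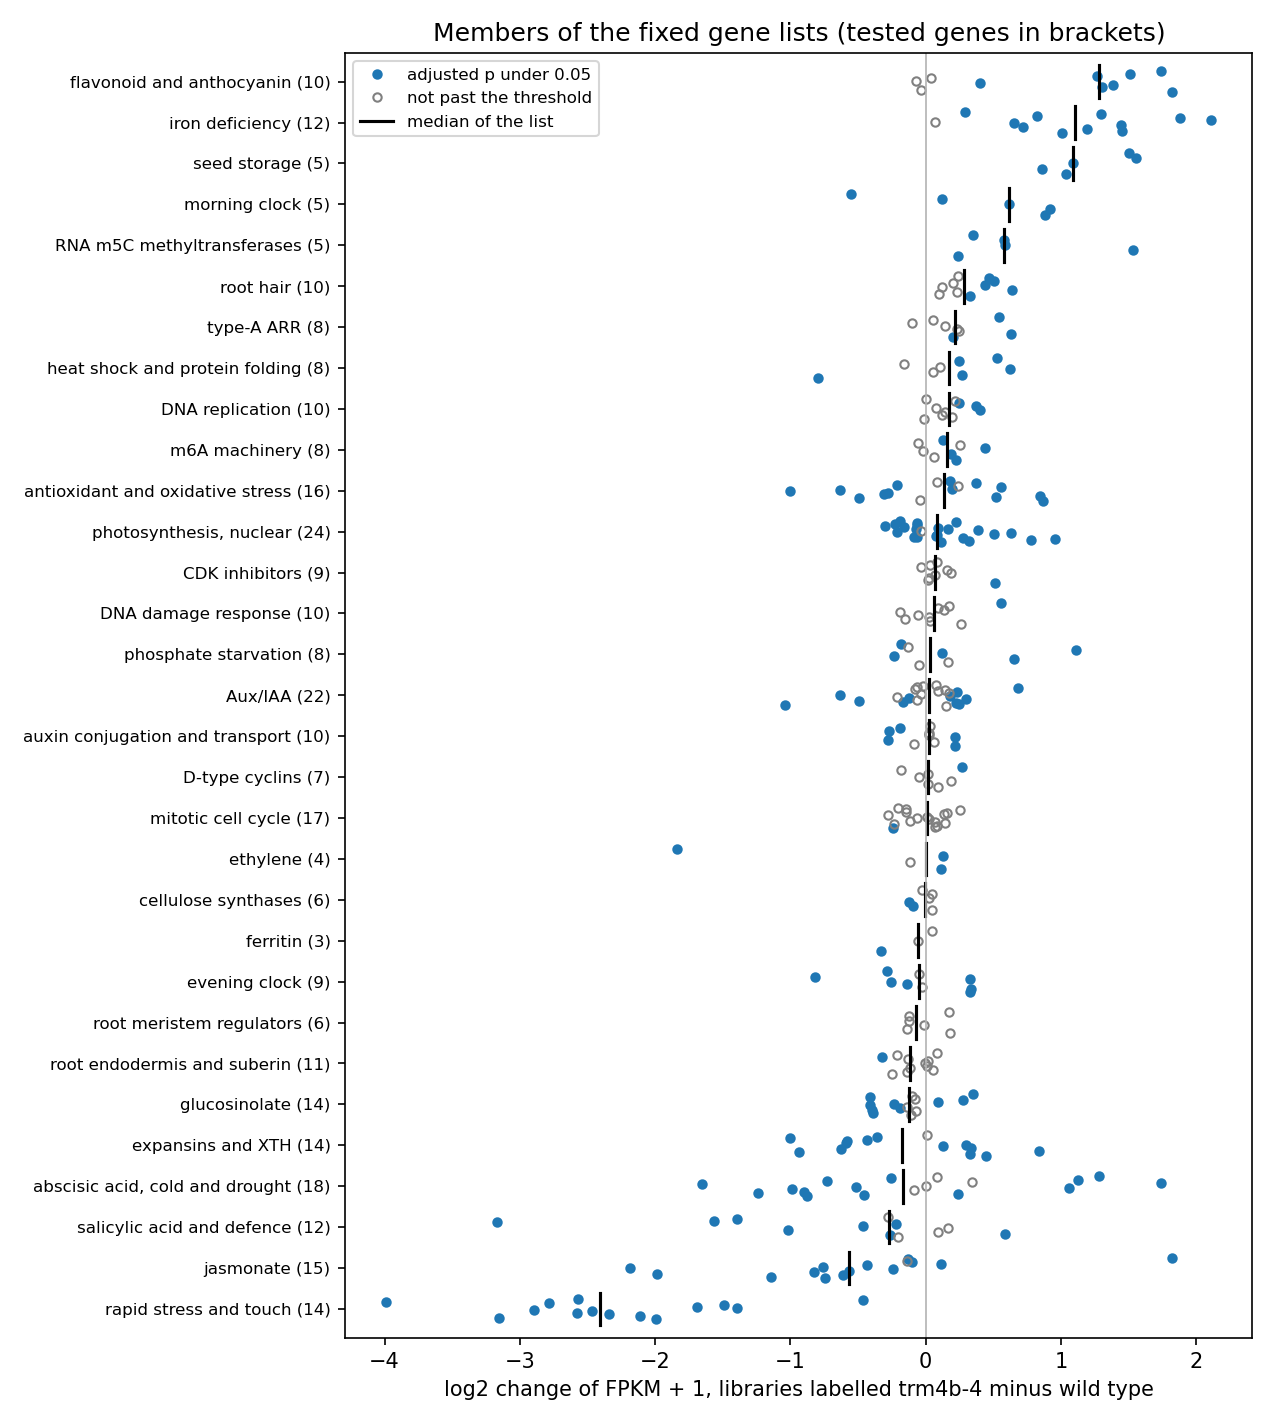
Log2 change (libraries labelled trm4b-4 minus wild type, FPKM + 1) of each tested member of the nuclear gene lists with at least 3 tested members, with the list's median as a vertical line. Filled points passed the gene test at an adjusted p under 0.05. The rapid stress and touch list has the lowest median, -2.40, and the flavonoid and anthocyanin list the highest, 1.28.

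Genes of the iron-deficiency response rose together, 11 of 12 tested, with a median of 1.1 (camera adjusted p = 7.27e-10, adjusted p = 0.332 with an estimated correlation). The regulator genes *bHLH38* and *bHLH39* went from 16.1 ± 0.321 to 73.1 ± 1.82 FPKM and from 26.9 ± 1.21 to 102 ± 2.37 FPKM. The root iron transporter gene *IRT1* and the ferric reductase gene *FRO2* rose by 0.82 and 1.01, and the member that did not pass was *F6'H1* (0.07, adjusted p = 0.306). Of the 3 ferritin genes, which encode iron stores, *FER4* fell (-0.33) and *FER1* and *FER3* were at 0.05 and -0.05 (camera adjusted p for the list 0.483). *FER4* lost its call without wild type replicate 1 (adjusted p = 0.0961) or trm4b-4 replicate 2 (0.0696). In the phosphate starvation list 3 of 8 rose, among them *SPX1* (1.11) and *PAP17* (0.65), and *PHO1* and *PHT1;1* fell (-0.23 and -0.18), with a camera adjusted p of 0.588.

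In the flavonoid and anthocyanin list 7 of 10 members rose and none fell, with a median of 1.28 (camera adjusted p = 0.00141, adjusted p = 0.524 with an estimated correlation). The regulator gene *PAP1* rose from 2.16 ± 0.52 to 10.1 ± 0.566 FPKM and the transport gene *TT19* from 2.39 ± 0.00603 to 7.14 ± 0.635 FPKM. *F3'H*, of an earlier step, rose by 0.40 (adjusted p = 0.0161). The members that did not pass, the chalcone synthase gene *CHS* (0.04), *CHI* (-0.04) and *FLS1* (-0.07), had adjusted p values of 0.353, 0.758 and 0.227. In the glucosinolate list 6 of 14 fell, including *MAM1* (-0.41) and *CYP79F1* (-0.39), and 3 rose, including *MYB28* (0.35) and *CYP79B2* (0.28). Its median was -0.12 (camera adjusted p = 0.0185, adjusted p = 0.54 with an estimated correlation), and the call was lost with quantile normalization (adjusted p = 0.0587). After median-of-ratios rescaling 8 fell and 2 rose, and with GC and length trends removed 9 fell and 2 rose.

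All 5 tested seed storage genes rose, from low levels, with a median of 1.09 (camera adjusted p = 0.000775, adjusted p = 0.54 with an estimated correlation). The oil-body gene *OLEO2* went from 0.524 ± 0.0585 to 3.48 ± 0.416 FPKM and the cruciferin gene *CRA1* from 0.103 ± 0.0758 to 2.13 ± 0.039 FPKM, with *EM1*, *EM6* and *PAP85* as the others. *CRA1*, *PAP85*, *EM1* and *OLEO2* were under 1 FPKM in both wild-type libraries and passed the filter only through the libraries labelled trm4b-4, so the direction of the tested members was largely set by the filter. Without a filter 6 of 8 tested seed storage genes rose and none fell (median 0.95, camera adjusted p = 4.01e-05), and with voom on recovered fragments the median of the 5 was 2.90. The other 7 fixed members were under the filter, and *SESA1* to *SESA4* together had 1 fragment in the 4 libraries. Genes of abscisic acid, cold and drought went both ways, 5 of 18 up and 9 down (median -0.17, camera adjusted p = 0.0592). With the stricter filter of 5 FPKM the median was -0.46 and the list passed (adjusted p = 0.00828). *RAB18* and *RD29B* rose by 1.28 and 1.13, and *COR15B* and *COR47* fell by 1.24 and 0.88 on the log2 scale.

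Among auxin genes, *SHY2* (AT1G04240, also IAA3), a repressor of auxin responses, was 39.0 ± 1.1 FPKM in wild type and 18.5 ± 1.15 FPKM in the libraries labelled trm4b-4 (SD, n = 2 each; log2 change -1.04, SE 0.053, limma adjusted p = 3.28e-06). *IAA16* (AT3G04730), of the same family, changed far less, from 199 ± 1.61 to 183 ± 0.517 FPKM (log2 change -0.12, adjusted p = 0.00364), and its call was lost without the mean-variance trend (adjusted p = 0.1). Of 22 tested Aux/IAA genes 6 rose, including *IAA13* (0.29) and *IAA29* (0.68), and 5 fell, including *IAA2* (-0.63), with a camera adjusted p of 0.641. Auxin conjugation and transport genes gave 2 rises, *PIN7* and *PIN4* (0.22 each), and 3 falls, including *GH3.5* (-0.27) and *LAX3* (-0.28), of 10 (camera adjusted p = 0.641). The type-A response regulators of cytokinin signalling had 3 of 8 members higher, *ARR6* (0.54), *ARR7* (0.63) and *ARR4* (0.20), and none lower (camera adjusted p = 0.111).

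None of the cell division and root meristem lists passed camera in the main test. Of 17 mitotic genes, *KNOLLE* alone passed the test (-0.24), and adjusted over the list alone none did (camera adjusted p = 0.551). *KNOLLE* was no longer called without wild type replicate 1 (adjusted p = 0.119) or trm4b-4 replicate 2 (0.0909), without a filter (0.0582) or without the mean-variance trend (0.0708). In the DNA replication list 3 of 10 rose, *TSO2* (0.37), *RNR1* (0.40) and *MCM7* (0.24), with a camera adjusted p of 0.0686 that passed the threshold without trm4b-4 replicate 1 (0.0393), and 5 rose with voom. *CYCD3;2* was the single call among 7 D-type cyclins (0.27), *KRP7* among 9 inhibitors of cyclin-dependent kinases (0.52) and *NAC103* among 10 DNA damage genes (0.56), and these lists had camera adjusted p values of 0.616, 0.469 and 0.658. *NAC103* lost its call without wild type replicate 2 (adjusted p = 0.0799) or trm4b-4 replicate 2 (0.0816). None of 6 tested root meristem regulators passed (camera adjusted p = 0.687), and the rest of the 11 fixed members were under the filter. Of 6 cellulose synthase genes, *CESA3* and *CESA1* fell slightly (-0.12 and -0.09, camera adjusted p for the list 0.455), and the fall of *CESA3* was not called without wild type replicate 2 (adjusted p = 0.0549) or without the mean-variance trend (0.111). *CESA1* lost its call without wild type replicate 2 (adjusted p = 0.168) or trm4b-4 replicate 1 (0.115), with quantile normalization (0.0561), without a filter (0.0559) and without the mean-variance trend (0.197).

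Of 10 root hair genes 5 rose, led by the cell wall genes *PRP3* (0.50) and *PRP1* (0.64) and followed by *ADF8*, *EXPA18* and *LRX1* (median 0.28, camera adjusted p = 0.0363, adjusted p = 0.54 with an estimated correlation). This list was no longer called without wild type replicate 2 (median 0.298) or trm4b-4 replicate 2 (median 0.304). The camera call was also lost with quantile normalization (median 0.25, adjusted p = 0.0611) and with the stricter filter (median 0.435, adjusted p = 0.0776). Without a filter 3 of its members rose. Among 11 endodermis and suberin genes *PER64* fell (-0.32) and none rose (camera adjusted p = 0.309), and *PER64* lost its call without wild type replicate 1 (adjusted p = 0.107) or trm4b-4 replicate 1 (0.0816) and without a filter (0.0551). The floral genes *SEP3* (-0.64, adjusted p = 0.000579) and *PI* (-0.09, adjusted p = 0.615) were too few for a list test. Expansin and xyloglucan-modifying genes went both ways, with 6 of 14 up, including *EXPA1* (0.84) and *EXPA4* (0.33), and 7 down, including *XTH4* (-0.62) and *XTH17* (-0.93) (camera adjusted p = 0.469).

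Nuclear photosynthesis genes split by gene, with 13 of 24 higher and 10 lower (camera adjusted p = 0.257). The list was called higher with voom on recovered fragments (adjusted p = 0.0463) and passed fry (adjusted p = 0.00776), and 6 members were lower without a filter. The antenna protein genes *LHCB1.1* and *LHCB1.2* rose by 0.95 and 0.78, and the Rubisco small subunit gene *RBCS2B* and the Rubisco activase gene *RCA* fell (-0.23 and -0.21). *LHCB1* and *RBCS* copies are nearly identical, so their single values are uncertain. Plastid-encoded transcripts were lower in 44 of 92 genes and higher in 17 (median -0.45, camera adjusted p = 0.00042, adjusted p = 0.744 with an estimated correlation), and fry gave no call (adjusted p = 0.372). Adjusted over the list alone, 51 were lower and 18 higher, and without a filter 29 of 100 were lower. The extremes were ATCG00220, which rose from 823 ± 72.6 to 2869 ± 120 FPKM, and ATCG00330, which fell from 46.1 ± 7.76 to 8.97 ± 1.36 FPKM. Mitochondrion-encoded transcripts fell in 20 of 35 genes and rose in none (22 fell adjusted over the list alone), with a median of -0.44 (camera adjusted p = 2.29e-06, adjusted p = 0.54 with an estimated correlation). Without a filter 21 of 84 mitochondrion-encoded transcripts fell and 2 rose, with a median of -0.25, and with voom 14 of 35 fell. Most organelle transcripts carry no stable poly(A) tail, so poly-T selection recovers them in part.

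Antioxidant and heat shock genes moved in both directions. Of 16 antioxidant genes 7 rose, including *CAT2* (0.37) and *AOX1A* (0.56), and 6 fell, including the copper/zinc superoxide dismutase gene *CSD2* (-1.0) and *GSTF8* (-0.64). The list's median was 0.13 while camera placed it lower (adjusted p = 0.943). In the heat shock and folding list 4 of 8 rose, including *MBF1C* (0.62) and *HSP90.1* (0.25), and *BIP3* fell (-0.80), with camera placing it higher (adjusted p = 0.469) and fry lower (adjusted p = 0.623).

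Adjusted over the list alone, the counts given for the lists were the same except where stated and in 5 others. These were 5 rises for N6-methyladenosine genes, 8 falls for salicylic acid and defence, 2 falls for heat shock, 4 rises for phosphate starvation and 7 falls for glucosinolate. In all, 11 of 33 lists passed camera at the preset correlation, 0 passed camera with an estimated correlation (3 at an unadjusted p under 0.05), and 18 passed fry.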

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

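Tests of recovered fragments (voom), of a 1.5-fold minimum and of GC and length trends were chosen after the results were seen. The count of changed genes, 6530, lay between 4678 and 5372 with a library left out, where the lone library of a genotype is assumed to vary like the other genotype, and between 4908 and 7524 under the other settings without a minimum fold. A test against a fold of 1.5 called 452 genes, 120 higher and 332 lower, and a minimum of 2-fold left 414, 114 higher and 300 lower. Both require a larger change on the log2(FPKM + 1) scale. Higher genes made up 55.9% of calls, 47% after median-of-ratios rescaling and 47.5% after GC and length trends were removed, so small changes do not show which direction prevails. Lists passing numbered 10 to 12 with a library left out and 9 to 15 otherwise, except 0 with an estimated correlation and 18 with fry, which test differently. *TRM4B* stayed called and higher under every setting run, with log2 changes of 1.48 to 1.58. Of the 10 genes beside it, 5 to 7 were called, but 0 against a fold of 1.5. Among the 20 nearest, 10 were called. No named gene or list turned its direction with a call. Over named genes and settings, 1641 results kept their side of the threshold and 87 lost the call, 57 of them against a fold of 1.5 and 16 with a library left out (4 and 5 without wild type replicates 1 and 2, 3 and 4 without trm4b-4 replicates 1 and 2). The remaining lost calls numbered 7 without the mean-variance trend, 3 without a filter, 2 with GC and length trends removed and 1 each with quantile normalization and median-of-ratios rescaling. Most named genes were picked for large changes or small adjusted p in the main fit, so they do not describe all calls. Of all 6530 calls, 4558 kept call and direction without the mean-variance trend and 5139 without a filter. With GC and length trends removed 5842 did, with quantile normalization 6036 and after median-of-ratios rescaling 5843. The abscisic acid list gained a call without wild type replicate 1 (0.0438) or trm4b-4 replicate 2 (0.0284), with the stricter filter (0.00828), voom (0.0101) and fry (0.0187), and the N6-methyladenosine list without trm4b-4 replicate 2 (0.0346) and with voom (0.0453). The DNA replication list gained one without trm4b-4 replicate 1 (0.0393), without a filter (0.0388), with voom (0.0439) and with fry (0.0456), and the nuclear photosynthesis list with voom (0.0463) and fry (0.00776). With fry alone the DNA damage and the endodermis and suberin lists (0.0456 each), morning clock (0.00363), ethylene (0.00332) and phosphate starvation (0.0454) passed. With voom, which adds less to low values, the seed storage median was 2.90 and the morning clock median 0.96. Medians of the Aux/IAA, auxin transport, D-type cyclin, mitotic, ethylene and cellulose synthase lists lay within 0.03 of 0 and changed sign or reached 0 with the scaling.

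Libraries with the same replicate number did not deviate together (correlation of deviations across genes -0.043). Both pairs give this same value, because the 2 libraries of a genotype deviate from their mean by equal and opposite amounts. With the replicate number as a block, 6769 genes (3768 higher, 3001 lower), 11 lists and 6 genes beside *TRM4B* were called, and *TRM4B* changed by 1.53 on the log2 scale. Genes near 1 FPKM have few fragments, and recovery was not simulated by expression level, so a missing call there does not show equal levels.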

Other observations

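Apart from the gene test and the fixed lists, the tests in this part were chosen after results of the gene test had been seen. Gene families were formed from product names in the TAIR10.1 annotation, 169 of them with at least 10 tested genes, and 11 passed camera. Of all 19027 tested genes 3648 rose and 2882 fell. Calcium-binding EF-hand genes fell in 15 of 30 cases with no rise (median log2 change -0.23, camera adjusted p = 1.12e-06), and TIR-NBS-LRR disease resistance genes in 15 of 41 with no rise (-0.15, adjusted p = 5.54e-06). Histone genes rose in 19 of 29 cases with no fall (0.22, adjusted p = 5.54e-06), DEA(D/H)-box RNA helicase genes in 13 of 18 with no fall (0.20, adjusted p = 0.0019) and TCP-1/cpn60 chaperonin genes in 10 of 12 with no fall (0.22, adjusted p = 0.0019). Pentatricopeptide repeat genes, many of which act on organelle RNA, rose in 41 of 173 cases and fell in 4 (0.20, adjusted p = 0.000526), with 31 rises after GC and length trends were removed, 25 without a filter and 70 with voom. Tetratricopeptide repeat-like genes rose in 78 of 244 cases and fell in 8 (0.17, adjusted p = 0.00062), the separately named PPR-like genes rose in 9 of 30 with no fall (0.22, adjusted p = 0.0109), ribosomal protein L7Ae/L30e/S12e/Gadd45 genes in 7 of 11 with no fall (0.25, adjusted p = 0.0019) and ubiquitin carboxyl-terminal hydrolase genes in 7 of 14 with no fall (0.32, adjusted p = 0.0109). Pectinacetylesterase genes fell in 5 of 11 cases with no rise (-0.22, adjusted p = 0.0217). With an estimated correlation each of these families had an adjusted p = 0.795, but that test has too few residual degrees of freedom to decide. The tetratricopeptide repeat-like genes had 58 rises after GC and length trends were removed and 97 with voom, where 13 fell. PPR-like genes had 16 rises with voom and 6 without a filter, and ubiquitin carboxyl-terminal hydrolase genes had 4 without a filter. The median of each kept its sign under the 5 other scalings run, with at most 1 EF-hand gene rising and at most 1 helicase and 1 chaperonin gene falling in any of them.

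Several genes outside the lists stood out. Of 51 genes with a late embryogenesis abundant product name 24 rose and 9 fell. These include 22 genes of the hydroxyproline-rich glycoprotein family that carries this name, of which 4 rose and 5 fell. The isocitrate lyase gene *ICL*, of the glyoxylate cycle, went from 7.49 ± 0.278 to 29.2 ± 0.203 FPKM (SD, n = 2 each). The neighbouring defensin-like genes AT1G13607, AT1G13608 and AT1G13609 rose by 1.43, 1.56 and 1.6 on the log2 scale. Of all 9 tested genes with a defensin product name 6 rose, 1 fell and 2 were not called. *PDF1.2* of the jasmonate list is among the 6. Like *M17* among the late embryogenesis abundant genes, it passed the filter only through the libraries labelled trm4b-4. Genes with at least 30 fragments in each library of a genotype and at most 3 in the other genotype numbered 4 in wild type and 2 in trm4b-4 by the labels. Besides *PRA8* and AT2G01422, AT1G33760 had 62 and 58 fragments in wild type and 1 and 0 in the libraries labelled trm4b-4, a ratio of 108 (exact 95% interval 19.0 to 4290). The unnamed feature Novel00022 had 34 and 40 against 0 and 0. It was 22.1-fold lower with a floor of 3 fragments over the group, and its exact 95% interval began at 17.5. In the other direction AT2G18190 had 2 and 0 fragments in wild type and 60 and 67 in trm4b-4 (ratio 70.8, interval 19.2 to 591), and the beta-glucosidase gene *BGLU19* had 2 and 1 against 41 and 56 (ratio 36.0, interval 12 to 178). Among the 3 nearest loci on each side of *PRA8*, AT3G13690 rose (0.22, adjusted p = 0.00436), *CYP90D1* (-0.09, adjusted p = 0.462) and AT3G13740 (0.14, adjusted p = 0.102) did not pass, and the others were not tested. Among those of AT2G01422, *PIN4* rose (0.22, adjusted p = 0.00166), *MPK17* fell (-0.63, adjusted p = 7.03e-06) and 4 did not pass.

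*TRM4B* was higher in the libraries labelled trm4b-4. Fragments of *TRM4A* counted for *TRM4B* are argued against as the source of this rise, since *TRM4A* itself rose by 1.29 FPKM. That was 2.25% of the rise of 57.4 FPKM in *TRM4B*. The reverse, *TRM4B* fragments counted for *TRM4A*, was not tested and could give the smaller rise of *TRM4A*. An insertion that starts transcription inside the gene may raise its fragment count without a full transcript. Transcription running past the gene may raise *RABA4E* (AT2G22390), which fell (log2 change -0.59). This does not decide, because the strand setting of the counting is not given and such transcription may stop before that gene. Transcription that ends within *TRM4B* cannot be told apart from a true rise without values per exon. A swap of all genotype labels also stays open, because the 2 genes that lost at least 100 fragments per library in trm4b-4 and the 0 that did so in wild type can be carried by either stock.

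The rapid stress and touch genes were lower in the libraries labelled trm4b-4, and a biological effect of the genotype was not separated from the harvest. A harvest at another time of day may contribute. Clock genes changed by a median size of 0.33 on the log2 scale, 4 of 5 morning genes upward, but the 9 evening genes went both ways, which decides nothing. More handling or wounding of the seedlings labelled wild type before harvest could give the same difference, and the 7 *JAZ* genes, which are not in that list, were all lower in trm4b-4 (median -0.83). The labels give no harvest or batch, so handling and genotype cannot be told apart.

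All 5 tested seed storage genes rose in the libraries labelled trm4b-4, a direction largely set by the filter. Seed tissue among the seedlings may be a source, but of the 7 storage genes outside the gene test 2, *CRU3* and *OLEO1*, were higher with an interval of the ratio above 1, and 4 had no fragment. The 7 together had 6 fragments in wild type and 70 in trm4b-4 (ratio 13.0, exact 95% interval 5.69 to 36.6), of which *CRU3* had 1 and 55, and without *CRU3* the ratio was 3.34 (interval 1.16 to 11.8). So few genes do not decide, and *SESA1* to *SESA4*, abundant in seeds, together had 1 fragment in the 4 libraries. A response of the whole seedling to abscisic acid stays open, since 27.8% of that list's members rose and others fell, and slower loss of seed storage transcripts in the mutant was not tested.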
